A study of Oryza sativa Japonica Group with 4 samples.

How the data were processed

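Panicle RNA of 4 rice groups was measured, with 1 array per group: wild type and the pola mutant at the early to late meiotic stage, and wild type and a POLA RNAi line at the ripening stage. Per the labels, 20 panicles from 10 plants were pooled for each sample, RNA was extracted with Trizol and labelled with biotin by the one-cycle Affymetrix protocol. The deposited values are intensity values, MAS5 signals on a linear scale per the submitters' processing notes. The MAS5 version, the scanner, the detection calls and the cultivar are not given in the sources used here. The values themselves were checked: none was below 0, and the 2% trimmed mean lay at 500.1 on each of the 4 arrays. The description of the RNAi sample names wild lines, while its title, source and genotype name the RNAi line; the latter was followed.

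The 187 control probe sets were set aside, 123 with the AFFX prefix and 64 reporter sequences, leaving 57194. A table of probe sets and genes paired 22531 of them with genes, 22436 with exactly 1 gene and 95 with several, and did not list 34663. Gene names came from a reference table of assembly GCF_034140825.1 (ASM3414082v1), used for names and for which genes neighbour each other only. It covered all 17905 genes, of which 2451 had a descriptive symbol. A gene was represented by its probe set with the highest mean signal over the 4 arrays. Probe sets with a name ending in _x_at were used only where the gene had no other.

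For each comparison the log2 ratio of signals was taken after adding a pseudocount of 23.4, the 25th percentile of all signals. A probe set was kept when the higher of its 2 signals reached the median of its own array, and a ratio of at least 1 in size was called a 2-fold difference. With 1 array per group no test was run and no p-value is given. The comparisons were mutant against wild type, RNAi line against wild type, and ripening against meiosis in wild type. The mutant and RNAi comparisons were set side by side by Pearson and Spearman correlation across probe sets and by the overlap of their differences.

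The gene lists, 30 in all, were written in advance, as words of gene descriptions and as symbols. They were translated to the symbols of the reference after its format was known and before any list value was computed. They held 546 genes, 7 symbols that belonged to unrelated genes were taken out, and 2 lists had fewer than 3 kept genes in every comparison with the filter above. A list's median log2 ratio was placed among 10000 random lists of as many genes, drawn from 20 bins of mean expression, as a description and not a test. A percentile in the lowest or highest 2.5% was used as the mark in the count of changed lists.

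Genes named in the text were chosen by a rule set in advance. It took the 8 highest and 8 lowest genes of each comparison with a descriptive name, a probe set paired with 1 gene and other kept probe sets going the same way. It added up to 3 genes past 2-fold from each list, and the 5 higher and 5 lower in both the mutant and RNAi comparisons. A second rule, added after the data were seen, took up to 8 genes each way among those past 2-fold under all 7 alternatives and above the 75th percentile. Other genes are named as chosen after their values were seen.

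The alternatives chosen before the data were examined were setting the median ratio to 0, quantile normalization, loess centring with a span of 0.3, a smaller pseudocount (5.85) or one of the median signal (103), no filter, a filter at the 75th percentile, a 4-fold threshold, and values per gene or averaged over probe sets. A common floor, raising every signal below 163 (the highest array median) to that value, was added after the dim signals of the arrays were seen to differ. Of these, 7 apply to single genes: the 3 scalings, both pseudocounts, the floor and the mean over probe sets.

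The steps were run on simulated data with 200.0 changed probe sets and a noise SD of 0.15 on the log2 scale, which was set by hand and not estimated from the arrays. In the simulated mutant, RNAi and stage comparisons alike, all 67 changes of 3-fold, all 67 of 4-fold and all 66 of 8-fold were recovered, and none of 28953, 29030 and 28947 unchanged probe sets was called. With so little noise and a 2-fold threshold this followed from the settings, so it checks the code and says nothing about the calls on these arrays. Of 1000.0 lists of 20 unchanged genes, 4.4%, 5.4% and 5.6% fell in the lowest or highest 2.5%. The simulation holds no difference in background between arrays, which the deposited arrays have. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.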

Results

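Gene expression was measured in panicles of rice, Oryza sativa Japonica Group, with Affymetrix arrays of 57194 probe sets besides controls. There were 4 groups with 1 array each. The first pair was wild type and the polaris (pola) mutant at the early to late meiotic stage. The second pair was wild type and a POLA RNAi line at the ripening stage, 10 to 15 days after pollination. Each array held the pooled RNA of 20 panicles from 10 plants. There were no replicates, so no difference given here has a replicate check and none was tested, and the number of arrays limits the precision of every value. Values are MAS5 signals on a linear scale, scaled to a 2% trimmed mean of 500.1 on every array, and differences are log2 ratios of these signals. The gene targeted by the mutation and the RNAi construct is not named in the tables used here, so its own signal is not given.

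The arrays had similar 75th percentiles and different medians. The median signal was 124 in wild type at meiosis and 51.8 in the mutant, 163 in wild type at ripening and 65.7 in the RNAi line, while the 75th percentiles lay between 487 and 521. The 27 hybridization control probe sets had median log2 ratios of 0.26 for mutant over wild type, 0.32 for RNAi line over wild type and 0.68 for ripening over meiosis in wild type. Many signals lay near background. Where the lower of 2 signals was below a common floor, the highest of the array medians (163), the log2 ratio depends on the pseudocount, and the fold with the floor is given as a lower bound for the leading genes. Across probe sets, the log2 signals of wild type and mutant correlated with a Pearson r of 0.94, and those of wild type and RNAi line with 0.906. The wild-type arrays of different stage correlated with 0.841, and the mutant and RNAi arrays, also of different stage, with 0.871. Probe sets of 1 array are not independent replicates. The ratio of the 3' to the 5' probe set of the GAPDH transcript was 2.04 and 2.01 on the wild-type arrays, 4.22 on the mutant array and 3.32 on the RNAi array. For actin it was 5.89, 8.06, 6.22 and 6.10 in the order wild type at meiosis, mutant, wild type at ripening and RNAi line. For cyclophilin it was 1.42, 1.86, 1.90 and 1.27, and for ubiquitin it lay between 0.766 and 0.796.

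**Figure D1:**
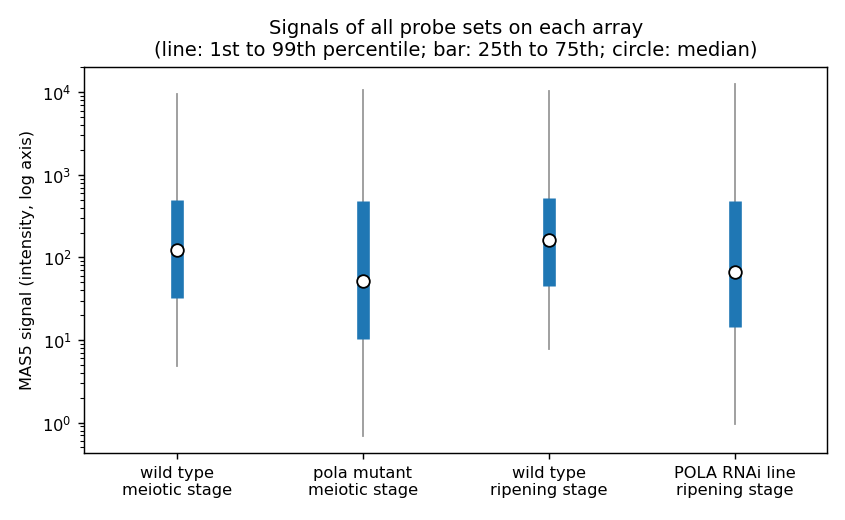
MAS5 signal (intensity, log axis) of all probe sets on each of the 4 arrays, with the line from the 1st to the 99th percentile, the bar from the 25th to the 75th and the circle at the median. The medians of the mutant and RNAi arrays, 51.8 and 65.7, lie below those of their wild types, 124 and 163.

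The comparison of wild-type panicles at ripening and at meiosis asks what distinguishes the stages in which the mutant and the RNAi line were sampled. Many genes of grain filling were higher at ripening. The glutelin gene GLUA-1 (LOC4327027) read 45837 at ripening and 17.2 at meiosis, at least 281-fold higher, with a log2 ratio of 10.14, and 8 of the 11 kept seed storage protein genes were higher, with a median log2 ratio of 8.74, or 7.35 with the common floor. Several genes of the anther were higher at meiosis. RTS (LOC4326940), a gene of the tapetum, the cell layer that feeds the developing pollen, read 17231 at meiosis and 31.7 at ripening, a log2 ratio of -8.29, or -6.72 with the common floor.

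Within the preset list of seed storage proteins, RA5 and RA14 rose at least 204-fold, a prolamin (LOC4342688) at least 186-fold, GLUA-3 at least 167-fold and GluC at least 158-fold. These are lower bounds, since the meiotic signals of all 5 were near background. Of 10 genes of oil bodies and late embryogenesis, 9 were higher at ripening and none lower, with a median of 5.22. On the log2 scale, the dehydrin gene RAB21 rose by 8.33, EM by 6.45 and LEA19 by 5.58. In starch synthesis, 5 of 10 genes were higher, with a median of 1.27: the granule-bound starch synthase GBSS1 rose by 6.49, the branching enzyme gene Q-enzyme by 4.20 and the starch synthase ALK by 4.15. All 4 kept amylase genes were higher, AMY1.4 by 5.47, AMY1.2 by 3.39 and AMY1.3 by 2.58. The sucrose synthase gene SUS4 rose from 611 to 12442 and the cell-wall invertase gene CIN1 from 40.2 to 966, within a list of sugar transport and sucrose use in which 10 genes were higher and 6 lower.

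Many defence and cold-response genes and some other stress genes were also higher at ripening. Of 16 defence proteins, 12 were higher and 2 lower, with a median of 3.32; the chitinase genes Cht4 and Cht2 rose by 6.98 and 6.35, and the chitinase gene Chia1d went the other way, from 14555 at meiosis to 29.2 at ripening. Of 14 cold and drought factors, 9 were higher and none lower, among them the cold-response regulators DREB1B with 4.12 and DREB1G with 4.11, and NAC6 with 3.43. The peroxiredoxin gene R1C-Prx rose by 8.73, the metallothionein gene MT4A by 3.78 and the catalase gene CAT-A by 3.61, in a list of 27 antioxidant genes with 8 higher and 2 lower. The small heat shock protein gene HSP16.9A rose by 6.13 and HS1 was lower with -2.48, which was -0.79 with the common floor, in a list of 40 heat shock genes with 14 higher and 5 lower. Outside the lists, the germin-like gene GER3 rose by 9.54 and Agglutinin by 8.82.

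Of 15 tapetum and pollen wall genes, 9 were lower at ripening and none higher, with a median of -2.60. CYP703A3, a hydroxylase of pollen wall formation, fell by 7.47 on the log2 scale, with C6 at -6.83 and C4 at -6.63. In the mitotic cell cycle, 6 of 7 genes were lower, with a median of -1.64, among them CYCA3-2 at -2.53, CYCB2 (LOC4342121) at -2.23 and CYCB1-1 (LOC4327547) at -1.72. Replication genes were lower in 5 of 28 cases and higher in 1, led by OsMCM6 with -1.86, and 2 of the 6 core histone genes, H2B.6 and H2B.10, were lower with -1.38 and -1.19. Of 54 cell wall genes, 24 were lower and 8 higher, with a median of -0.77. Among 11 meiosis genes, 3 were lower: MEL1, an argonaute of germ cells, with -3.83, SPO11-4 with -1.50, and PAIR1 with -2.03, which was 0.00 with signals below a common floor raised to it. The argonaute gene AGO1D fell by 3.29. Ratios against dim signals were smaller with the common floor, among them GER3 with 7.81, R1C-Prx and RAB21 with 7.13, Agglutinin with 6.92, Cht4 with 6.02, Cht2 with 5.56, AMY1.4 with 4.34, AMY1.2 with 1.59, AMY1.3 with 1.57, DREB1B with 3.73, DREB1G with 3.40, MADS21 with 3.52, C6 with -6.59, CYP703A3 with -5.30, OsMCM6 with -1.55 and CYCA3-2 with -1.26.

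MADS-box regulators, which include the genes of floral organ identity, split by member. Of 25 kept genes, 10 were lower and 7 higher at ripening, with a median of -0.66 that became -0.01 with the same common floor. MADS29 rose from 39.3 to 2902, MADS21 by 4.34 on the log2 scale and MADS13 from 562 to 2464. In all, 6040 probe sets were at least 2-fold higher at ripening and 4812 lower among the 33129 kept by the filter. The balance turned with other scalings, to 5679 higher and 6197 lower after quantile normalization and 5087 higher and 5366 lower after loess centring. Over all genes, 1692 higher and 1897 lower ones kept their 2-fold difference under each of the 7 alternatives applied to single genes. Where a called gene had other kept probe sets, all went the same way for 552 of 663 genes, or 83.3%.

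**Figure D2:**
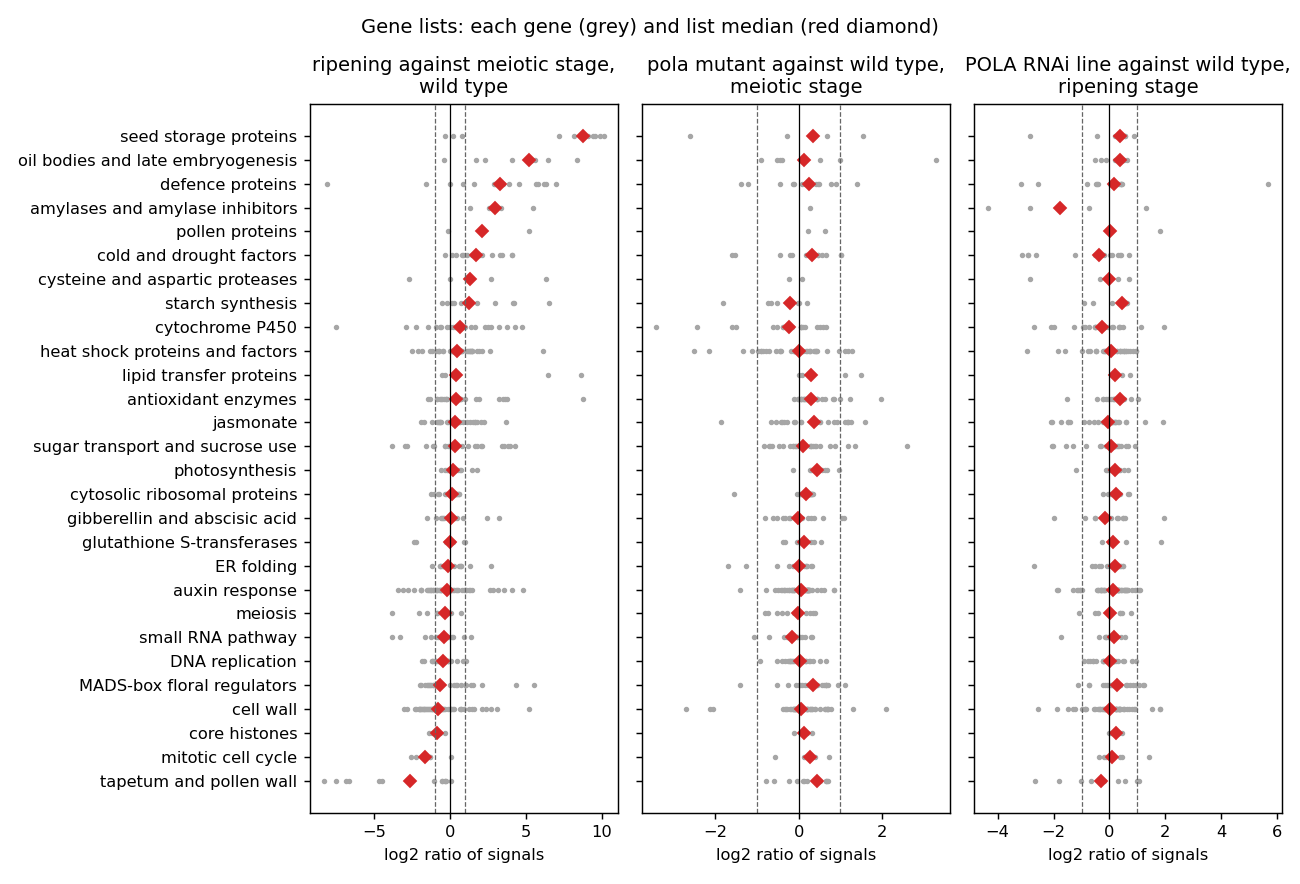
Log2 ratio of signals for each kept gene of the preset lists (grey points) and list medians where at least 3 genes were kept (red diamonds), in each of the 3 comparisons, with dashed lines at 2-fold. The medians run from -2.60 for tapetum and pollen wall to 8.74 for seed storage proteins between the stages, and most lie near 0 in the mutant and RNAi comparisons.

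The comparison of the pola mutant with wild type at meiosis asks which transcripts differ when the gene is mutated. Jasmonate repressor genes, a dehydrin gene and a gene of melatonin synthesis were among those higher in the mutant. JAZ11 (LOC4331833), a repressor of the jasmonate response, read 1286 in the mutant and 530 in wild type, a log2 ratio of 1.24. The dehydrin gene RAB21 (LOC4350454) read 668 and 47.5, at least 4.09-fold higher, and ASMT1 (LOC4346795), the melatonin gene, read 462 and 17.9, at least 2.83-fold higher. The pyruvate decarboxylase gene PDC (LOC4339066) fell from 564 to 71.7, at least 3.45-fold.

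Of 25 kept jasmonate genes, 6 were higher and 1 lower. Besides JAZ11, the higher ones were JAZ12 with 1.18, JAZ13 with 1.17, JAZ10 with 1.12, JAZ5 with 1.59 and the reductase gene OPR4 with 1.18, and JAZ2 was lower with -1.86. Without a filter, 6 of 31 jasmonate genes were higher and 4 lower, with a median of 0.04 at percentile 74.4 of random lists. With the filter, the list median was 0.38 against a median of 0.05 for random lists of like expression. It lay at percentile 100 of 10000 such lists, and fell to 0.07 and percentile 86.2 with the common floor. Most of the genes named here were bright enough for this floor to leave their signals as they were: JAZ12 read 1460 in wild type and 3334 in the mutant, and JAZ13 read 1459 and 3304. JAZ5 and JAZ2 were dim and no longer passed 2-fold with it. JAZ10, JAZ12, JAZ13 and OPR4 were singled out after their values were seen.

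Genes of the anther were present in both arrays. None of the 15 tapetum and pollen wall genes passed 2-fold, and their median of 0.43 lay at percentile 100 of the random lists, whose own median was 0.11; it was 0.17 after quantile normalization. RTS read 28011 in the mutant and 17231 in wild type, C4 read 28210 and 20228, and C6 read 21610 and 15787. None of the 13 kept meiosis genes passed 2-fold, and MEL1 read 1858 and 2276. Their median was -0.03, and it was 0.29 after quantile normalization and 0.27 after loess centring. With the 75th percentile filter, which kept 5 of them, it was -0.29 at percentile 1.085. Of 25 MADS-box genes, MADS21 was higher with 1.10 and MADS27 lower with -1.40, both under 2-fold with the common floor, and the list median was 0.34 at percentile 100. None of 12 photosynthesis genes passed 2-fold, with a median of 0.44 at percentile 100. Small RNA pathway genes had a median of -0.16 at percentile 0.32, with AGO3 at -1.07 as the 1 gene past 2-fold of 17, which read -0.66 after quantile normalization.

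Among single genes, the iron transporter gene IRT1 rose by 2.64, the cell-wall invertase gene CIN1 by 2.59, the expansin gene EXP1 by 2.10, the galactolipid synthase gene MGD2 by 1.99, the metallothionein gene MT-1-4b by 1.96 and TIP1 by 1.90. Lower genes included CYP99A3 at -3.41, a cytochrome P450 of diterpene synthesis, the related CYP99A2 at -2.44, OsC3H40 at -3.11, the expansin gene EXPB18 at -2.68, GLUB-4 at -2.60, CRK10 at -2.55, HSP21.9 at -2.50 and WRKY62 at -2.47. Many of these were dim. With the common floor, IRT1, MGD2, MT-1-4b, TIP1, CYP99A3, CYP99A2, EXPB18, GLUB-4, CRK10, HSP21.9 and WRKY62 no longer passed 2-fold, and CIN1 had 1.14, EXP1 1.44 and OsC3H40 -1.25.

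A second naming rule, added after the values were seen, took the extreme genes among those that passed 2-fold under all 7 alternatives and were brighter than the 75th percentile. It named RAB21, the salt-responsive lectin gene ML (LOC4326471) with 9125 in the mutant and 2921 in wild type, the germin-like gene GER2 with 1661 and 521, CFBP1 with 520 and 157, the protein phosphatase gene PP2C30 with 1017 and 331, UGE-3 with 2760.5 and 959, DAO with 2833 and 1067, and the aquaporin gene OsPIP2;4 with 1281 and 508. It named PDC and BC1L9 as lower, the latter with 142 in the mutant and 882 in wild type.

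The count of probe sets was 1045 higher and 5425 lower of 32291 kept, so 83.8% of the differences were lower in the mutant. With the labels of both meiotic arrays exchanged it would be 16.2%. This share depended on scaling: it was 52.4% after quantile normalization, with 2463 higher and 2710 lower, and 32.3% after loess centring, with 3016 higher and 1439 lower. With the 75th percentile as filter there were 224 higher and 195 lower. The 95 control probe sets for sequences not from rice had a median log2 ratio of -0.98 in the same comparison, with median signals of 5.36 in the mutant and 36.5 in wild type. Under all 7 alternatives, 97 genes stayed 2-fold higher and 63 lower, and other kept probe sets of a called gene went the same way for 85 of 134 genes.

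The comparison of the POLA RNAi line with wild type at ripening asks which transcripts differ in the grain-filling panicle when the gene is silenced. Several cold-response genes and 2 amylase genes were among those lower in the RNAi line, and jasmonate genes went both ways. AMY1.3 (LOC4345814) read 48.2 in the RNAi line and 485 in wild type, at least 2.97-fold lower, and DREB1B (LOC4347618) read 264 and 2171, a log2 ratio of -2.93. METK3 (LOC4325163), an S-adenosylmethionine synthase gene, read 67.2 and 1822, at least 11.2-fold lower. The chitinase gene Chia1d (LOC4338720) read 2679 and 29.2, at least 16.4-fold higher.

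Of 4 kept amylase genes, 2 were lower and 1 higher, with a median of -1.77 at percentile 0.03 of the random lists. AMY1.2 fell from 491 to 1.85, and AMY1.5 rose from 302 to 783. The fifth measured member did not pass the filter, and without a filter the list median was -0.72 at percentile 10.9. Of 15 cold and drought factors, 5 were lower and none higher: DREB1G with -3.14, DREB1B with -2.93, CBF1 with -2.90, CBF3 with -2.62 and DREB1E with -1.25. Their list median was -0.36 at percentile 2.10, which was 7.53 without a filter and 3.04 with the median signal as pseudocount. Of 27 jasmonate genes, 6 were lower and 2 higher, with a median of -0.06 at percentile 13.4, and with quantile normalization and loess centring alike 5 were lower and 4 higher. The lower ones were JAZ9 with -2.06, JAZ13 with -1.41, OPR12 with -1.73, LOX2 with -1.49, LOX1.1 with -1.47 and the allene oxide synthase gene AOS (LOC4332121) with -2.09, and JAZ2 rose by 1.92. CBF3, DREB1E, JAZ13, OPR12, LOX2, LOX1.1 and C4 were singled out after their values were seen.

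The products of grain filling differed little. None of the 10 starch synthesis genes passed 2-fold, and their median of 0.44, at percentile 99.2, was 0.17 after quantile normalization. GBSS1 read 28232 in the RNAi line and 18917 in wild type. Of 11 seed storage protein genes, 1 passed 2-fold, GLUB-4 with -2.83, which was -0.06 after loess centring. The list median was 0.39 and became 0.00 after quantile normalization and 0.02 after loess centring. No gene of oil bodies and late embryogenesis passed 2-fold, with a median of 0.37 that was 0.10 after quantile normalization and 0.11 after loess centring. Antioxidant genes had a median of 0.38 at percentile 99.8, which was 0.06 at percentile 83.1 after quantile normalization, and among them the metallothionein gene MT-1 rose from 9014 to 18103.

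Hormone genes went both ways. The abscisic acid hydroxylase gene ABA8OX1 fell from 3087 to 754, and the gibberellin synthesis gene KAO rose by 1.96. Of 53 auxin response genes, 7 were lower and 2 higher, led by PIN5 with -1.87, GH3.1 with -1.83 and IAA31 with -1.29. The balance turned to 4 higher and 2 lower after quantile normalization and to 5 higher and 2 lower after loess centring. The sucrose transporter gene SUT5 was lower with -2.05, SUS5 with -2.04 and SWEET1B with -1.55, the list of sugar transport and sucrose use holding 4 lower and no higher genes of 28, which became 2 lower and 1 higher after loess centring and 2 lower and none higher with the common floor. Among 16 defence genes, the chitinase genes LOC4351188 and Chib3H-a were lower with -3.16 and -2.55. The glutathione transferase gene GST1 rose from 346 to 1292.5 and the expansin gene EXPB10 from 182 to 692. Of 10 kept tapetum and pollen wall genes, BURP13 with -2.66, PTC1 with -1.80 and C4 with -1.02 were lower and MTR1 was higher with 1.04, and the list median of -0.29 changed sign to 0.07 after quantile normalization and loess centring.

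Other genes with large differences were OsC3H40, which rose from 129 to 3867, the aquaporin gene OsPIP2;4, which rose from 41.9 to 1241, BURP2 with 2.63, CPK22 with 2.40, PUB24 with 2.22, LPR2 with 2.10 and HXK3 with 2.06. The iron transporter gene YSL15 was lower with -3.05, the germin-like gene GLP2 with -3.01 and HSF02 with -2.95, and LA fell from 185 to 2.61. With the common floor, CPK22, PUB24, HXK3, YSL15, LA, HSF02, CBF1, AOS, LOX1.1, KAO, PIN5, SUS5, Chib3H-a, GLUB-4, BURP13 and C4 no longer passed 2-fold, and neither did MT-1 after quantile normalization, with 0.65. With the floor, OsPIP2;4 had 2.93, BURP2 1.34, LPR2 1.37, GLP2 -1.80, LOC4351188 -1.95, AMY1.2 -1.59, CBF3 -2.27, SUT5 -1.58, SWEET1B -1.48, GH3.1 -1.40 and PTC1 -1.21. The second naming rule added AldC-alpha, with 530 in the RNAi line and 138 in wild type, the trehalose phosphatase gene TPP7, with 380.4 and 2173, and ACA7, with 149 and 807.

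In total, 1614 probe sets were higher and 7030 lower of 33157 kept, so 81.3% of the differences were lower in the RNAi line. After quantile normalization there were 3894 higher and 4278 lower, and after loess centring 4111 higher and 2134 lower, or 34.2% lower. The 95 control probe sets for sequences not from rice had a median log2 ratio of -1.06, with median signals of 7.53 in the RNAi line and 52.6 in wild type. Under all 7 alternatives, 172 genes stayed 2-fold higher and 291 lower, and other kept probe sets of a called gene went the same way for 137 of 212 genes.

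The mutant and RNAi comparisons share no array, but differ in stage and in how the gene was disturbed. The mutant and RNAi arrays both had lower medians and higher GAPDH 3' to 5' ratios than their wild types. For actin and cyclophilin the ratio was higher on the mutant array only. With 1 array per group, a shared trait of arrays or RNA cannot be told apart from a shared effect of the gene. Set side by side, the germin-like gene GER2 was higher in both, with 1.63 in the mutant and 1.75 in the RNAi line, as were OsPIP2;4 with 1.30 and 4.27, BURP2 with 2.24 and 2.63, GLU5 with 1.44 and 1.46, and PDX12 with 1.51 and 1.41. PDC (LOC4339066) was lower in both, with -2.63 and -2.44, as were GLUB-4 with -2.60 and -2.83, the kinase gene wjumk1 with -2.29 and -2.41, the nicotianamine synthase gene NAS2 with -2.06 and -2.40, and the ammonium transporter gene AMT3-1 with -2.42 and -1.96. With the common floor, GER2, OsPIP2;4 and PDC stayed past 2-fold in both comparisons, and the other genes did not.

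Across the 28427 probe sets kept in both, the log2 ratios correlated with a Pearson r of 0.61 and a Spearman rho of 0.47. Of 3103 probe sets past 2-fold in both, 2981 went the same way, or 96.1%: 175 were higher in both, where independent lists would share 27.7, and 2806 lower in both, where they would share 641. With the labels of both meiotic arrays exchanged, r would be -0.61 and 3.93% would go the same way. Few of the shared differences lay in bright probe sets. In the probe sets above the 75th percentile of mean signal the Pearson r was 0.07, and 45 of 86 went the same way. Above the 90th percentile r was -0.02, and 4 of 14 went the same way. With the 75th percentile filter r was 0.21, and 64 of 79 went the same way. Of these, 22 were higher in both, where independent lists would share 2.37, and 42 lower in both, where they would share 2.04. With the common floor r was 0.34, and 272 of 301 went the same way. The r was 0.48 after quantile normalization and 0.41 after loess centring, and 91.7% went the same way with each.

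The difference between ripening and meiosis was taken again from the other pair of arrays, the RNAi line at ripening against the mutant at meiosis, which shares no array with the wild-type pair. Seed storage proteins had a median of 9.24 there, oil bodies and late embryogenesis 5.02, starch synthesis 1.84, tapetum and pollen wall -2.81 and the mitotic cell cycle -1.62. The log2 ratios of both pairs correlated with a Pearson r of 0.85 across 28220 probe sets, and with 0.927 above the 75th percentile of mean signal. Of 6398 probe sets past 2-fold in both, 6273 went the same way. If the labels of both meiotic arrays were exchanged, wild type at meiosis would be the array labelled mutant. Ripening would then have 10252 higher and 4864 lower probe sets, with medians of 8.72 for seed storage proteins and -2.37 for tapetum and pollen wall.

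Among the 64 reporter control probe sets, which detect sequences not from rice, 2 stood apart. The probe set for X17220 read 28361 on the RNAi array and 5117 on the wild-type array at meiosis, against 2.24 on the mutant array and 53.4 on the wild-type array at ripening. The probe set for K01193 read 8881 on the RNAi array and between 8.52 and 28.3 on the other 3. The highest of the other 62 reporter probe sets was 94.2 on the RNAi array and 344 on the wild-type array at ripening.

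**Figure D3:**
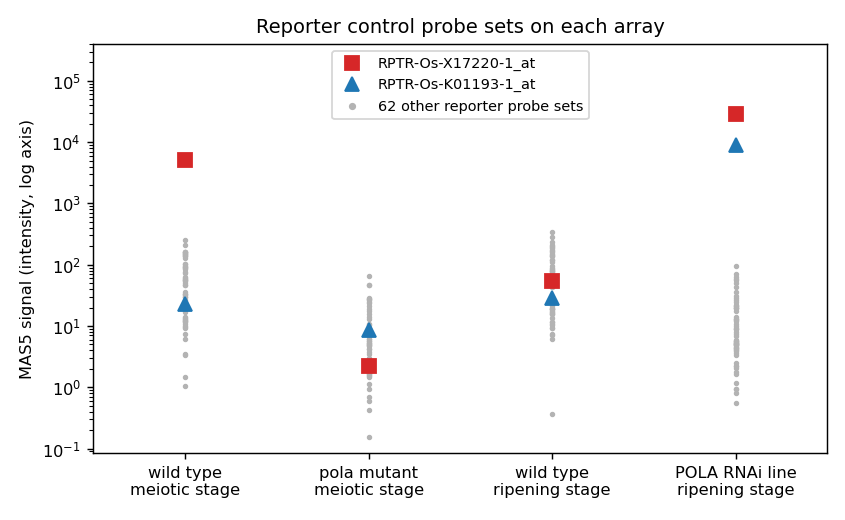
MAS5 signal (intensity, log axis) of the reporter control probe sets on each of the 4 arrays, with red squares for X17220, blue triangles for K01193 and grey points for the other 62. X17220 reads 28361 on the RNAi array and 5117 on the wild-type array at meiosis, and K01193 reads 8881 on the RNAi array.

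A set of 19 probe sets was low on the mutant array and well above it elsewhere, at least 4-fold below the lowest of the other 3 arrays after the common floor. The rule was chosen after the values were seen. The same rule gave 5 probe sets for the wild-type array at meiosis, 11 for the wild-type array at ripening and 10 for the RNAi array. Those of the 19 that were paired with 1 gene covered 9 genes. The others, among them 1 that read 32.6 on the mutant array and 7608 in wild type at meiosis, do not enter the gene counts. LOC4349197 read 145 on the mutant array and 3055 in wild type at meiosis, LOC4350782 read 336 and 4622, LOC4349255 read 187 and 3604, and LOC9267585 read 10.2 and 1287. BC1L9 (LOC4349011), LOC4349257, LOC4350817, LOC4340728 and LOC4325216 were the others, and the reference gives a descriptive symbol for BC1L9 alone.

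**Figure D4:**
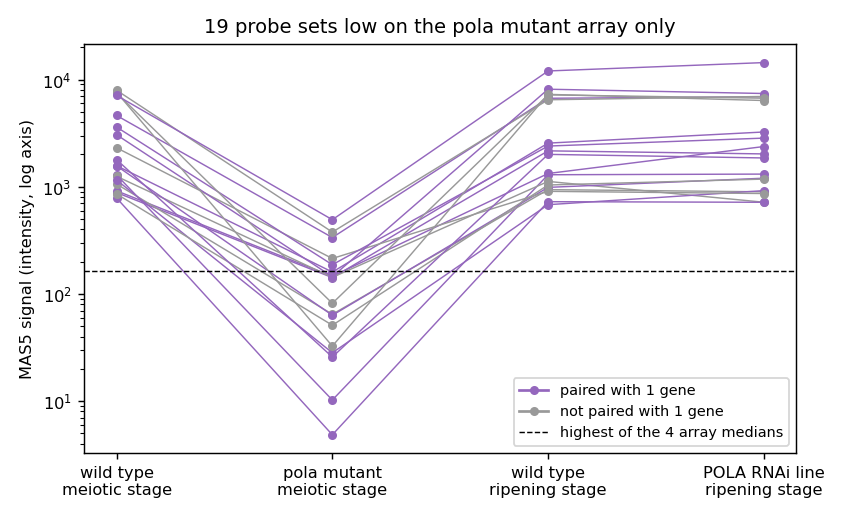
MAS5 signal (intensity, log axis) on each of the 4 arrays for the 19 probe sets low on the mutant array, 1 line per probe set, purple where it is paired with 1 gene and grey where it is not, with a dashed line at 163, the highest of the array medians. LOC4349197 reads 145 on the mutant array and 3055 in wild type at meiosis.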

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

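The tests in this part were chosen after the results were seen, except those of the genes between neighbouring low genes and of further probe sets, which were written before their values were computed.

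Several genes moved in opposite directions in the mutant and RNAi comparisons, which differ in stage, and the difference was not tested for any of them. MT-1-4b had log2 ratios of 1.96 in the mutant and -1.52 in the RNAi line, OsC3H40 -3.11 and 4.67, CRK10 -2.55 and 1.72, MADS27 -1.40 and 1.22, and JAZ2 -1.86 and 1.92. With the common floor, OsC3H40 alone of these was past 2-fold in both, with -1.25 and 4.57. It read 387 in wild type at meiosis, 24.2 in the mutant, 129 in wild type at ripening and 3867 in the RNAi line, so it was high and low on the same arrays as X17220 below. With the labels of both meiotic arrays exchanged, these 5 genes would move the same way in both comparisons. This follows from choosing them for opposite signs, so it is no sign of an exchange. The 5 were taken from the genes named by rule. JAZ13, singled out after its values were seen, also moved in opposite directions, with 1.17 in the mutant and -1.41 in the RNAi line. Its signals lay above the common floor on all arrays: 1459 in wild type at meiosis, 3304 in the mutant, 867 in wild type at ripening and 311 in the RNAi line. Among control probe sets, which no comparison used, X17220 read 28361 on the RNAi array and 5117 on the wild-type array at meiosis, and K01193 read 8881 on the RNAi array, all above the highest of the other reporter probe sets.

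The first pattern is the excess of lower over higher probe sets in the mutant and RNAi comparisons. A lower level of dim signals on the mutant and RNAi arrays is a candidate explanation: control probe sets for sequences not from rice had median log2 ratios of -0.98 and -1.06, and above the 75th percentile of signal the share of lower differences was 46.5% and 57.2%. The pseudocount shrinks these ratios, as the median signals of these controls were 5.36 against 36.5 and 7.53 against 52.6. The same dim signals may underlie part of the correlation between both comparisons, since the Pearson r above the 75th percentile of mean signal was 0.0702. Above the 90th percentile it was -0.02, and 4 of 14 probe sets past 2-fold in both went the same way. With the 75th percentile filter it was 0.21, and 64 of 79 did. Across the 28427 probe sets kept in both, r was 0.48 after quantile normalization and 0.41 after loess centring, but these include the dim ones. With the common floor r was 0.34, and 272 of 301 probe sets past 2-fold in both went the same way. Whether the level comes from hybridization, scanning or processing was not tested. An effect of the mutation or the silencing on dim transcripts remains open for dimmer genes.

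The second pattern is the signal of X17220 and K01193. RNA of the RNAi line mixed into the wild-type sample at meiosis is argued against: at the 18.0% share seen for X17220, K01193 would read 1602 there and GLUA-1 10812, and they read 23.1 and 17.2. An exchange of the labels of both meiotic arrays cannot be told apart from a foreign sequence in the wild-type sample, since X17220 read 2.24 on the array labelled mutant and the tables do not name the targeted gene; the 19 probe sets low on the array labelled mutant alone, against 5 on the array labelled wild type, go the way of the labels, as with LOC9267585 at 10.2 against 1287 there and 1294 in wild type at ripening, but the cultivar of the lines is not given and these were chosen for being low. A foreign sequence carried by the RNAi line, such as a transformation vector, could account for the RNAi array, because both probe sets lay within the range of the others (at most 344) on the wild-type array at ripening. If the labels of the meiotic arrays were exchanged, every log2 ratio of the mutant comparison would change sign, its lower share would be 16.2%, its Pearson r with the RNAi comparison -0.61, and 3.93% of the probe sets past 2-fold in both would go the same way, and the stage comparison would take the array labelled mutant as wild type, with 10252 higher and 4864 lower probe sets.

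The third pattern is the 9 genes low on the mutant array alone, of which LOC4349197, LOC4349255 and LOC4349257 lay close together along a chromosome, as did LOC4350782, LOC9267585 and LOC4350817. A lower level of dim signals on the mutant array was set against their placing, and no conclusion is drawn from it. Distance was counted among the 7043 measured genes at least 4-fold above the common floor on every other array. There, 4 neighbouring pairs, at most 25 such genes apart, were reached in 1 of 10000 random draws. The criterion was first more pairs than the highest draw, which that draw tied, so by it dim signals were not excluded. It was replaced, after this result, by under 500 of 10000 draws, because the highest draw rises with the number of draws. The rule had also already left out genes dim on the other arrays, so their placing cannot decide this. A missing continuous segment is argued against, since the 17 other measured genes between neighbouring low genes had a median log2 ratio of 0.24 (quartiles -0.04 and 0.40). Sequence differences under single probe sets may account for some, as 1 of the 4 genes with a further probe set had it within 2-fold, a small number. Other genes had 2 probe sets low on the mutant array: LOC4340728 with 4.85 and 25.8, LOC4349257 with 28.2 and 63.2, and LOC4349255 with 187 and 492. A difference under a single probe set would not cover both in LOC4340728 and LOC4349255, unless their probe sets share sequence, which was not checked. Both probe sets of LOC4349257 bear the same name up to its ending, so 1 difference may lie under both. A biological difference between the lines stays open and untested.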

How the results depend on the processing

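All alternatives were planned except the common floor, which was chosen after the data were seen. No paired analysis was possible because each group had 1 array. The cause was not tested unless given. Counts are of probe sets, higher then lower. In the mutant comparison (1045 and 5425), quantile normalization gave 2463 and 2710, loess centring 3016 and 1439, and the median signal as pseudocount 287 and 3047. The 75th percentile filter gave 224 and 195, the common floor 319 and 649, the 4-fold threshold 85 and 2235, and values per gene 364 and 702. Without a filter, 13194 were lower. In the RNAi comparison (1614 and 7030), quantile normalization gave 3894 and 4278, loess centring 4111 and 2134, the 75th percentile filter 431 and 575, the common floor 603 and 2024, the 4-fold threshold 273 and 3461, and values per gene 594 and 1185. The median signal as pseudocount gave 636 higher, and no filter 16713 lower. Between stages (6040 and 4812), the 75th percentile filter gave 2601 and 2937, the 4-fold threshold 2239 and 1585, and values per gene 2480 and 2636. No filter gave 9674 higher and the common floor 3708 higher. Fewer probe sets enter with the stricter filter and values per gene, more enter without a filter, and the 4-fold threshold calls fewer of the same ones. The Pearson r between the mutant and RNAi comparisons was 0.211 with the 75th percentile filter and 0.343 with the common floor. Setting the median to 0 and the smaller pseudocount left all counts within 1.5 times.

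List medians moved into or out of the lowest or highest 2.5% of random lists as follows. In the mutant comparison, with the 75th percentile filter, defence proteins read 0.76, heat shock 0.26, meiosis -0.29 and mitotic cell cycle 0.27. Defence proteins read 0.27 with the smaller pseudocount, 0.53 with loess centring and 0.56 with quantile normalization. Starch synthesis read -0.22 with loess centring, -0.20 with the median signal as pseudocount and -0.21 with quantile normalization. Mitotic cell cycle read 0.20 with both loess centring and quantile normalization. Cold and drought factors read 0.60 with loess centring, 0.00 with the common floor and 0.016 without a filter, jasmonate 0.066 and 0.044 with the latter settings, and antioxidant enzymes 0.21 with the common floor and 0.11 with quantile normalization. Seed storage proteins read 0.34 without a filter. In the RNAi comparison, the 75th percentile filter gave auxin response 0.28, cytochrome P450 -0.25 and oil bodies 0.44. Cytochrome P450 read -0.20 with the common floor and -0.26 with quantile normalization. Antioxidant enzymes read 0.073 and starch synthesis 0.17 with loess centring, and 0.055 and 0.17 with quantile normalization. Cold and drought factors read -0.27 with the median signal as pseudocount and -0.28 without a filter, where amylases read -0.72. Between stages, the 75th percentile filter gave auxin response -0.43, DNA replication -0.41, cytochrome P450 0.34 and sugar transport 0.31. Sugar transport read 0.37 with the smaller pseudocount, 0.32 with loess centring, and 0.31 with the median signal as pseudocount and with quantile normalization. Jasmonate read 0.41 with loess centring and 0.47 with quantile normalization. With the common floor, MADS-box regulators read -0.012, cytochrome P450 0.28 and pollen proteins 0.16. Pollen proteins read 1.16 with the median signal as pseudocount and 1.71 with quantile normalization, which gave heat shock 0.29. Without a filter, MADS-box regulators read -0.012 and cytochrome P450 0.31.

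Among named genes, loess centring reversed Chib3H-h in the mutant, to 0.068, and LA, CYP76M7 and CP1 in the RNAi comparison, to 0.052, 0.36 and 0.28. The common floor took 39 named genes of the mutant comparison, 31 of the RNAi comparison and 5 of the stage comparison below 2-fold, since signals under it become equal. Signal over background limits what can be said of genes below the array medians.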

Other observations

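The tests of clock and calmodulin-like genes in this part were written before their values were computed, and the count with the common floor was chosen after the result was seen.

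Further gene groups moved between the stages in wild type. Of 55 auxin response genes, 15 were lower and 11 higher at ripening, with SAUR39 at 4.84, GH3.2 at 4.07 and GH3-8 at 3.58. Cytochrome P450 genes were higher in 9 and lower in 4 of 24 cases, led on the higher side by CYP71Z7 with 4.77 and CYP701A8 with 4.27. The lipid transfer protein genes LTP-2 and LTP rose by 8.65 and 6.45. The pollen protein gene EXPB9, a beta-expansin, rose by 5.20, the aspartic protease gene ASP1 by 6.35 and the cysteine protease gene SAG12 by 2.71, and the aspartic protease gene AP25 fell from 10412 to 1619. The peroxidase genes PRX112 and LOC4339222 had log2 ratios of 5.92 and -5.99. Of 18 ER folding genes, PDIL1-4 and PDIL1-1 were higher with 2.67 and 1.32, and PDIL5-4 was lower with -1.15. Cytosolic ribosomal proteins had a median of 0.13 with 2 of 24 genes lower, and the list of gibberellin and abscisic acid genes had ABA8OX1 at 3.24 and SLRL1 at 2.43. Raising dim signals to the common floor gave LTP-2 7.18, LTP 6.02, PRX112 5.19, EXPB9 4.33, ASP1 4.29, CYP71Z7 4.12, CYP701A8 3.93, GH3.2 3.78, SAUR39 3.10, SAG12 1.75, SLRL1 1.70 and LOC4339222 -5.07, since the lower signal of each lay under it.

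Several groups had medians near 0 in the mutant and RNAi comparisons. Cytosolic ribosomal proteins had medians of 0.18 and 0.24, which were -0.02 and -0.03 after quantile normalization. Core histones had 0.12 and 0.24, with no gene past 2-fold. The mutant value was -0.06 after quantile normalization and -0.05 after loess centring, and the RNAi value was 0.11 and 0.12. Replication genes had 0.04 and 0.01 with no gene past 2-fold. Their RNAi value was 0.18 after quantile normalization and 0.15 after loess centring, each with 2 genes higher. The gibberellin synthesis gene GA20OX3 read 2067 in the mutant and 992 in wild type, a ratio of 1.04 that was 0.94 after quantile normalization. The photosynthesis gene RBCS fell from 658 to 275 in the RNAi line.

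A hypothesis was tested for the lower cold-response and jasmonate genes of the RNAi line, that handling at harvest differed. A lower level of dim signals on the RNAi array is argued against for most, since 8 of the 11 genes stayed 2-fold lower with the common floor. A different time of day at harvest was predicted to move at least 2 of 7 clock genes past 2-fold, and 0 of 7 passed. Their median was 0.20 at percentile 73.9, with CCA1 at 0.53, PRR37 at 0.50 and PCL1 at -0.24. A shift too small to move them 2-fold is not excluded. The count was 0 in the mutant and stage comparisons too, so whether it can pick up a time difference here is not known. Touch or wounding at harvest may contribute: the calmodulin-like genes had a median of -0.26 at percentile 0.16 of the random lists, with 3 of 22 lower and 1 higher. This percentile was not taken with the common floor, and the median rests in part on dim signals. With the floor, CML24 went from -0.98 to -0.18, CML11 from -0.51 to 0.00 and the higher gene CML3 from 1.20 to 0.00. The lower genes CML15, CML16 and CML31 stayed past 2-fold, with -1.39, -1.33 and -2.03. An effect of the silencing itself stays open, and handling and silencing would both differ between the same 2 arrays.

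Chia1d, which was high on both meiotic arrays, read 2679 in the RNAi line, or 18.4% of its signal in wild type at meiosis. RTS, BURP13, CYP703A3, C6, C4, PTC1 and MEL1 read 3.08, 20.9, 33.6, 34.9, 77.9, 91.9 and 133 in the RNAi line, all under the common floor, so no share is given for them.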
